A study of Mus musculus with 3 samples.

How the data were processed

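Single-cell RNA was profiled in 3 libraries of mouse glioma tissue, 1 each for control, Glo1 knockdown and Glo1 overexpression. Per the labels' protocols, tissue was dissociated with papain and DNase I, red blood cells and debris were removed, and dead cells were removed where necessary. Libraries were made with the Chromium Single Cell 3′ v4 kit and sequenced on a NovaSeq 6000. The submitters' processing notes name Cell Ranger 3.0.2, Seurat 4.1.0 and the build mm10. Which of these made each file, the cell-calling threshold, the filters on cells, any doublet removal and the clustering settings are not given in the sources used here. Whether the genes changed by the manipulation of Glo1 took part in the clustering is not given either, so a cluster that sits mostly in 1 library may be that library rather than a cell type. All 3 libraries were put in the same batch here, which does not show that they were processed together. The number of animals behind each library is not stated in the labels.

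Of the files used, a cell annotation of the whole series gives each cell's barcode, library and cluster number as deposited by the authors. A list per library gives the deposited cell barcodes of 16 bases, and a second list gives the genes that were counted. None of these values is a measurement of expression. Expression values, counts of unique molecules per cell, cell type names, cell-cycle phases and embedding coordinates were not analysed here. The comparisons planned for cell types were therefore made for clusters, and no gene, phase, depth or doublet analysis was run. The depth behind each share is the number of annotated cells, 33080 in control, 25241 in knockdown and 62448 in overexpression. At these numbers the floor of 3 counts, used in ratios for a count of 0, is a share of 0.00907%, 0.0119% and 0.00480%. No columns were left out as belonging to other samples.

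Cells were assigned to conditions by the library name in the annotation, which matches the library name in each sample's description. A cell was taken as listed when its barcode, without the library prefix, was on its own library's barcode list. Shares per cluster were computed over all annotated cells of a library, with exact Clopper-Pearson intervals at the 95% level. Each pair of libraries was compared by the ratio of shares. A rule fixed before the data were examined named a cluster as higher or lower where the ratio was at least 1.5, the intervals did not overlap and at least 50 cells were in 1 of the 2 libraries. No p-value was computed, since each condition has 1 library and cells are not replicates. The difference between 2 libraries was summarised as the percent of cells that would have to change cluster. Its interval came from 1000 multinomial draws, and it was set against 1000 draws of equal libraries. The rule was tested on simulated data with 33 clusters, of which 8 were changed, in libraries of the sizes of the knockdown and control libraries. In 200 draws it found 91.2% of the 2-fold gains, 100.0% of the 4-fold gains and 100.0% of the losses. These folds were set before all shares were rescaled to a common total, so the simulated ratios of shares differed from them. Between control and an unchanged library of the size of the overexpression library, it called 0.0152% of clusters. The draws held counting error only, with no variation between libraries.

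Alternatives were the removal of the largest cluster, fixed in advance, and settings added after the barcode lists had been compared with the annotation. The added ones were listed cells only, all listed barcodes as the denominator, removal of barcodes seen in another library, a centred log ratio with a pseudocount of 0.5, removal of clusters with over 80% of their cells from 1 library, and removal of clusters with under 50% of their pooled cells listed. By the 80% limit, clusters 0, 8 and 32 were left out, with 84.1%, 93.8% and 92.4% of their cells from overexpression. Cluster 27 was left out too, with 88.8% from control. By the 50% limit, clusters 0, 1, 2, 5, 10, 12 and 15 were left out. Gene identifiers were matched to GENCODE M21 on GRCm38, the assembly that mm10 denotes. Of the 33696 identifiers, 32012 were found there and 1684 were not. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.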

Results

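Single-cell RNA sequencing was run on glioma tissue dissected from the GFP-positive tumour regions of mouse brain. There were 3 conditions, a control, a knockdown of Glo1 and an overexpression of Glo1, with 1 library each. Glo1 encodes glyoxalase 1, an enzyme of methylglyoxal detoxification, and the study's title ties it to the transcriptional networks of Sox2, a stem-cell transcription factor, in glioma stem-like cells. The question open to these data was how the cell clusters of the tumour were distributed under less and under more Glo1. The deposited annotation assigned 120769 cells to 33 clusters numbered from 0 to 32, which it did not name, and which held from 66 to 35076 cells each. The control library contributed 33080 annotated cells, the knockdown library 25241 and the overexpression library 62448. With 1 library per condition there was no replicate check and no test. Each share is given with its exact 95% Clopper-Pearson interval, which covers counting error only. A cluster was called higher or lower only where its shares differed at least 1.5-fold, their intervals did not overlap and 1 of the libraries held at least 50 of its cells.

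In each library the annotated cells and the deposited list of cell barcodes overlapped only in part, and the overexpression library stood apart from the other libraries in this. The lists held 25492 barcodes for control, 20099 for knockdown and 26139 for overexpression. Of the annotated cells, 10035 in control (30.3%, interval 29.8 to 30.8%) and 7380 in knockdown (29.2%, 28.7 to 29.8%) carried a barcode that was not on the list. In overexpression 44947 annotated cells did so (72.0%, 71.6 to 72.3%). The cells that were both annotated and listed numbered 23045, 17861 and 17501 in control, knockdown and overexpression. These are called listed cells hereafter, and each comparison is given for all annotated cells and for listed cells. The annotated barcodes of each library matched their own list far more often than the others: 17501 overexpression barcodes were on the overexpression list, 472 on the control list and 347 on the knockdown list.

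**Figure D1:**
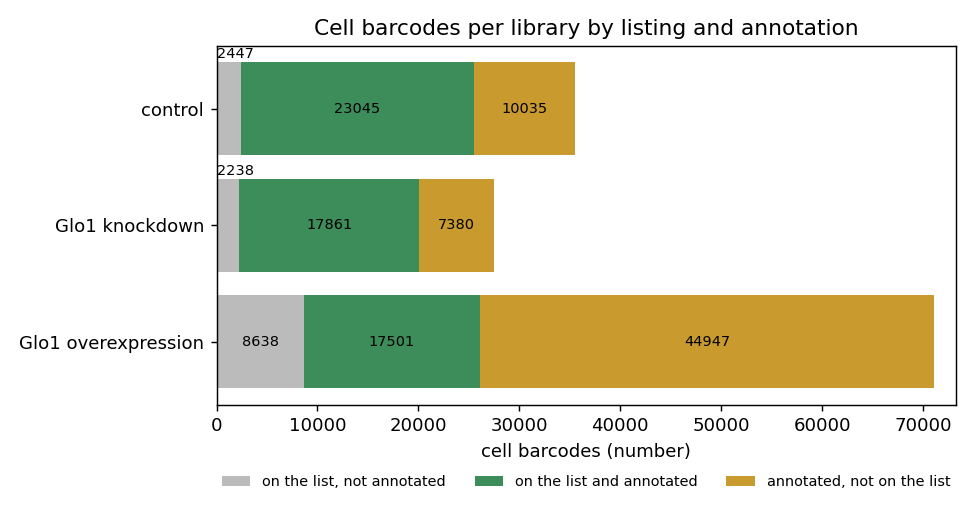
Number of cell barcodes (x axis) in each of the 3 libraries (y axis), divided into listed but not annotated, listed and annotated, and annotated but not listed. The last part held 44947 barcodes in overexpression, against 10035 in control and 7380 in knockdown.

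Knockdown of Glo1 was compared with control. Clusters 2, 8, 19, 21, 25, 26 and 28 took a higher share of the knockdown cells. Cluster 2, the largest of them, held 15.6% of the knockdown cells (15.2 to 16.1%) and 9.44% of the control cells (9.13 to 9.76%), a 1.65-fold difference. Cluster 8 held 0.681% (0.584 to 0.791%) against 0.145% (0.107 to 0.192%), 4.70-fold higher, and cluster 28 held 0.384% against 0.106%, 3.63-fold higher. Clusters 19, 21, 25 and 26 were 2.01-fold, 1.78-fold, 2.48-fold and 2.27-fold higher. Clusters 1, 10, 16, 22, 27, 29 and 30 took a lower share. Cluster 1 held 4.77% of the knockdown cells (4.51 to 5.04%) and 13.3% of the control cells (13.0 to 13.7%), 2.79-fold lower. Cluster 27 was lower by the widest margin, 9.26-fold, with 15 knockdown cells (0.0594%, 0.0333 to 0.0980%) and 182 control cells (0.550%, 0.473 to 0.636%). Clusters 10, 16, 22, 29 and 30 were 2.15-fold, 3.08-fold, 1.64-fold, 1.66-fold and 2.48-fold lower. The large clusters 3, 7 and 9 passed no call: they held 16.3%, 4.77% and 4.88% of the knockdown cells and 13.7%, 4.72% and 4.93% of the control cells. Cluster 4 passed none either, with 3037 of the 25241 knockdown cells and 3528 of the 33080 control cells. All 14 calls were also made among listed cells, where clusters 0 and 12 were called higher and cluster 5 lower in addition. Cluster 29 was the only one of the 14 that lost its call under another setting. The 2 libraries would match if 17.0% of the cells of one changed cluster (interval 16.4 to 17.9%). Simulated libraries of equal composition, with counting error only and no variation between libraries, reached at most 2.59%.

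Overexpression of Glo1 was compared with control. Cluster 8 was higher and clusters 9, 18, 22 and 27 were lower, in all annotated cells and in listed cells. Cluster 8 held 5.31% of the overexpression cells (5.14 to 5.49%) and 0.145% of the control cells (0.107 to 0.192%), a 36.6-fold difference that widened to 90.6-fold among listed cells, at 17.3% against 0.191%. Its overexpression cells went only from 3317 to 3028, while that library's denominator fell from 62448 to 17501. The control denominator fell less, from 33080 to 23045. For mostly listed clusters this raises gains and shrinks losses among listed cells. The 2 sets share cells and are not independent. Cluster 11 was also higher, at 2.29% against 1.35%, 1.69-fold, and among listed cells at 8.12% against 1.94%, 4.20-fold. Cluster 32 had 61 overexpression cells (0.0977%, 0.0747 to 0.125%) and 0 of 33080 control cells (0 to 0.0112%). Against a floor of 3 control cells, 0.00907%, it was 10.77-fold higher, which is a ratio to that floor and not a lower limit. Cluster 9 held 0.0993% of the overexpression cells (0.0761 to 0.127%) and 4.93% of the control cells (4.70 to 5.17%), 49.7-fold lower, and 22.1-fold lower among listed cells. Clusters 18, 22 and 27 were 11.1-fold, 32.8-fold and 42.9-fold lower, and 4.92-fold, 19.2-fold and 17.3-fold lower among listed cells. The 2 large clusters 3 and 4 held 2.64% and 1.57% of the overexpression cells against 13.7% and 10.7% of the control cells. Among listed cells they held 9.43% and 5.60% against 19.7% and 15.3%. Clusters 19, 24, 25, 26, 29, 30 and 31 were lower in both sets as well.

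Cluster 0 was the largest group of the overexpression library and depended on the barcodes used. It held 47.2% of all annotated overexpression cells (46.8 to 47.6%), against 8.72% in control (8.42 to 9.03%) and 10.7% in knockdown (10.3 to 11.1%). Among listed cells it held 1.55% (1.38 to 1.75%), 0.391% (0.314 to 0.480%) and 0.717% (0.598 to 0.852%). Of the 29486 cluster 0 cells in overexpression, 272 were listed. Among all annotated cells 4 clusters were called higher and 21 lower in overexpression, while among listed cells 10 were higher and 13 lower. All 4 higher calls and 13 of the 21 lower calls were shared by both sets. Clusters 1, 5, 15, 16, 20 and 28 were called higher among listed cells but not among all annotated cells, by 1.71-fold, 1.64-fold, 2.29-fold, 3.70-fold, 3.03-fold and 2.60-fold. The libraries would match if 45.5% of all annotated cells (45.1 to 46.1%), or 39.0% of listed cells, changed cluster. Clusters 6, 7, 12, 13, 14, 17, 21 and 23 were lower among all annotated cells and passed no call among listed cells, where clusters 12, 13 and 14 lay at or above control.

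**Figure D2:**
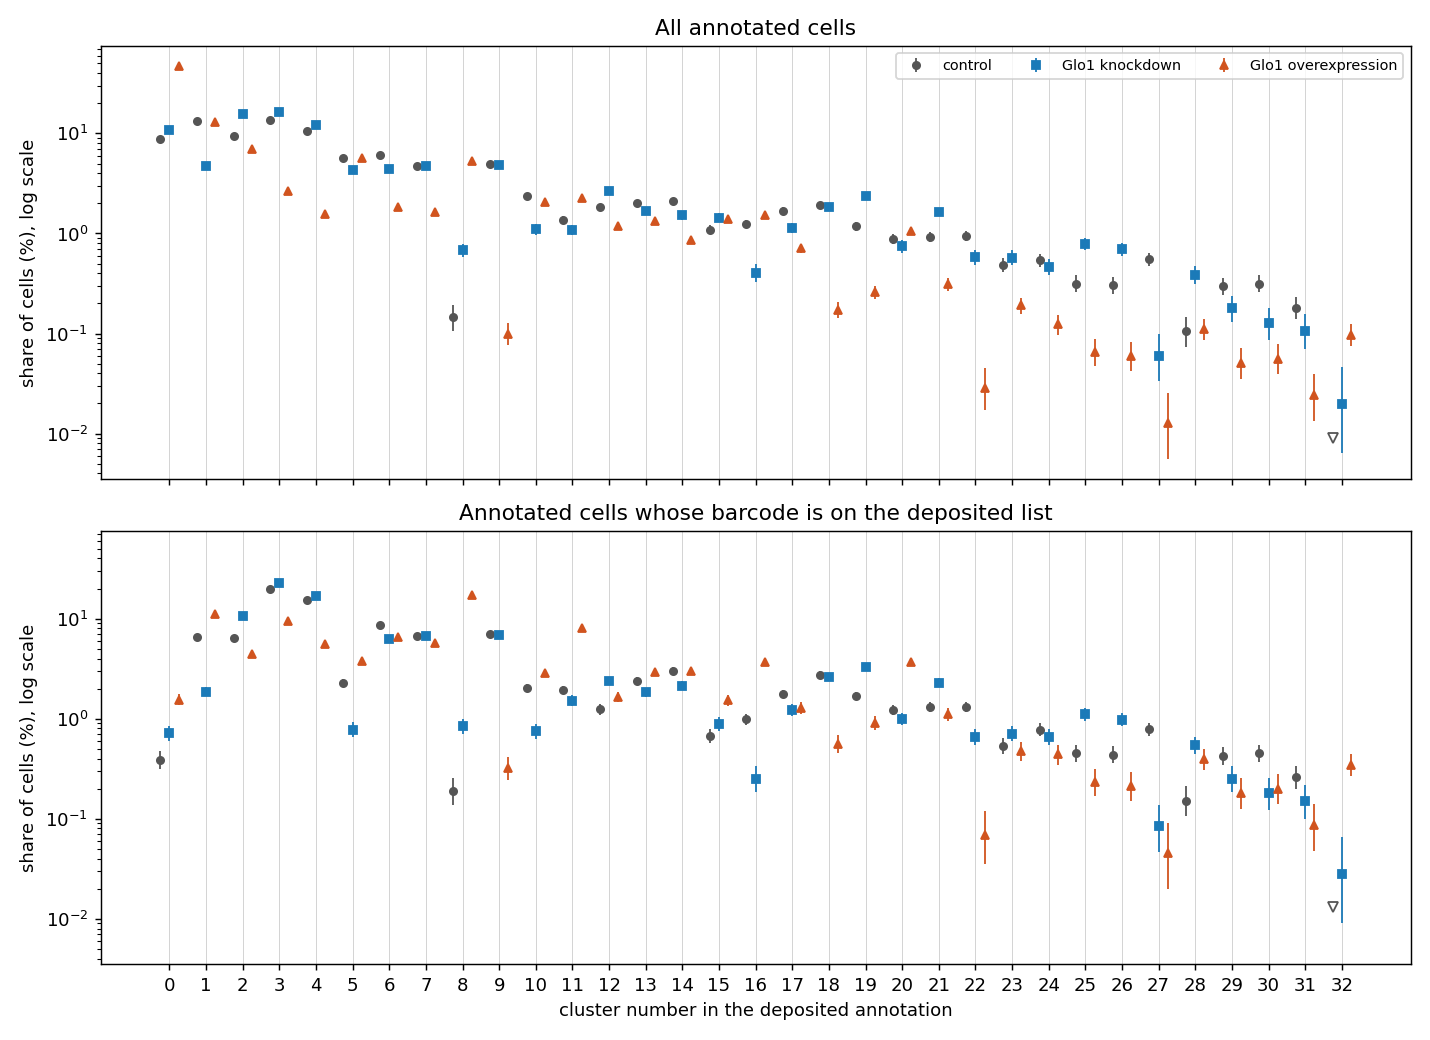
Share of cells in percent on a log scale (y axis) for each cluster (x axis) in control (circles), knockdown (squares) and overexpression (triangles), for all annotated cells above and listed cells below. Bars are exact 95% intervals for counting error, and the open triangle marks the floor of 3 counts for the 0 control cells of cluster 32. Cluster 0 in overexpression drops from 47.2% to 1.55% between the panels, while cluster 8 rises from 5.31% to 17.3%.

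The 2 manipulated libraries were compared directly. Cluster 9 was 49.1-fold higher in knockdown than in overexpression, at 4.88% (4.61 to 5.15%) against 0.0993% (0.0761 to 0.127%), and 21.5-fold higher among listed cells. Clusters 22, 25, 26, 18 and 19 were 20.1-fold, 11.9-fold, 11.7-fold, 10.6-fold and 9.24-fold higher in knockdown. Among listed cells the same 5 clusters were 9.64-fold, 4.71-fold, 4.63-fold, 4.64-fold and 3.60-fold higher. Cluster 16 held 0.404% of the knockdown cells (0.330 to 0.490%) and 1.54% of the overexpression cells (1.45 to 1.64%). Cluster 1 held 4.77% and 12.9%, cluster 10 held 1.10% and 2.07%, and cluster 11 held 1.09% and 2.29%. All 4 were called lower in knockdown in both sets, and clusters 16, 1, 10 and 11 were 3.82-fold, 2.71-fold, 1.89-fold and 2.11-fold lower among all annotated cells and 14.5-fold, 5.98-fold, 3.83-fold and 5.35-fold lower among listed cells. Clusters 8, 32 and 0 were also called lower in both sets. They were 7.79-fold, 4.93-fold and 4.40-fold lower among all annotated cells and 20.6-fold, 12.5-fold and 2.17-fold lower among listed cells. In total 18 clusters were higher and 7 lower in knockdown among all annotated cells, and 10 were higher and 11 lower among listed cells. Matching these libraries would require 54.4% of all annotated cells (53.8 to 55.0%) or 47.9% of listed cells to change cluster.

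Opposite moves under less and under more Glo1 were looked for next. Clusters 19, 25 and 26 were higher in knockdown and lower in overexpression than in control, in both sets of cells, and cluster 21 was so among all annotated cells but not among listed cells. Cluster 19 held 2.38% of the knockdown cells (2.20 to 2.58%), 1.18% of the control cells (1.07 to 1.30%) and 0.258% of the overexpression cells (0.220 to 0.301%). Among listed cells it held 3.27% (3.01 to 3.54%), 1.69% (1.53 to 1.86%) and 0.909% (0.773 to 1.06%), so its loss in overexpression was 1.86-fold there and 4.58-fold among all annotated cells. Clusters 1, 5 and 16 were lower in knockdown and higher in overexpression among listed cells but not among all annotated cells. Clusters 1, 10 and 16 were so without the largest cluster, by centred log ratio and without clusters mostly from 1 library. With all listed barcodes as the denominator, cluster 16 alone was. Cluster 16 was so too without clusters mostly off the list, where clusters 1, 5 and 10 were left out and could not be called. Among listed cells, cluster 16 held 0.252% (0.184 to 0.337%), 0.989% (0.866 to 1.13%) and 3.66% (3.38 to 3.95%) of the knockdown, control and overexpression cells. Other clusters moved the same way in both: cluster 8 was higher and clusters 22, 27, 29 and 30 lower in both libraries and in both sets of cells. Clusters 0 and 28 were higher in both libraries among listed cells but not among all annotated cells. Cluster 28 was also higher in both without the largest cluster, by centred log ratio, without clusters mostly from 1 library and without clusters mostly off the list. The 4 clusters that were higher in knockdown and lower in overexpression compare with 4.45 for independent lists of the same lengths, and the 4 that were lower in both also compare with 4.45. Among 200 simulated sets of unchanged libraries around the same control composition, with counting error alone, the highest number in any of these classes was 0. The rule for a call already removes counting error, so that outcome was fixed in advance and decides nothing. Both comparisons used the same control library, so part of any such overlap may come from it.

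Clusters differed widely in how many of their cells were listed. At least 90% of the cells were listed in every library that held them for 20 of the 33 clusters. Clusters 0, 1, 2, 5 and 15 had fewer than 50% of their cells listed in every library. In cluster 0 the listed share was 3.12% in control (2.52 to 3.82%), 4.73% in knockdown (3.96 to 5.60%) and 0.922% in overexpression (0.817 to 1.04%). In cluster 2 it was 47.6% in control and 47.8% in knockdown but 17.7% in overexpression (16.6 to 18.9%). Cluster 8 was mostly listed in all 3, at 91.7% of the 48 control cells, 87.2% (81.3 to 91.8%) and 91.3% (90.3 to 92.2%). The effective number of clusters, the exponential of the Shannon entropy of the shares, was 17.0 in control, 15.8 in knockdown and 7.85 in overexpression. Among listed cells it was 16.1, 14.4 and 17.2.

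**Figure D3:**
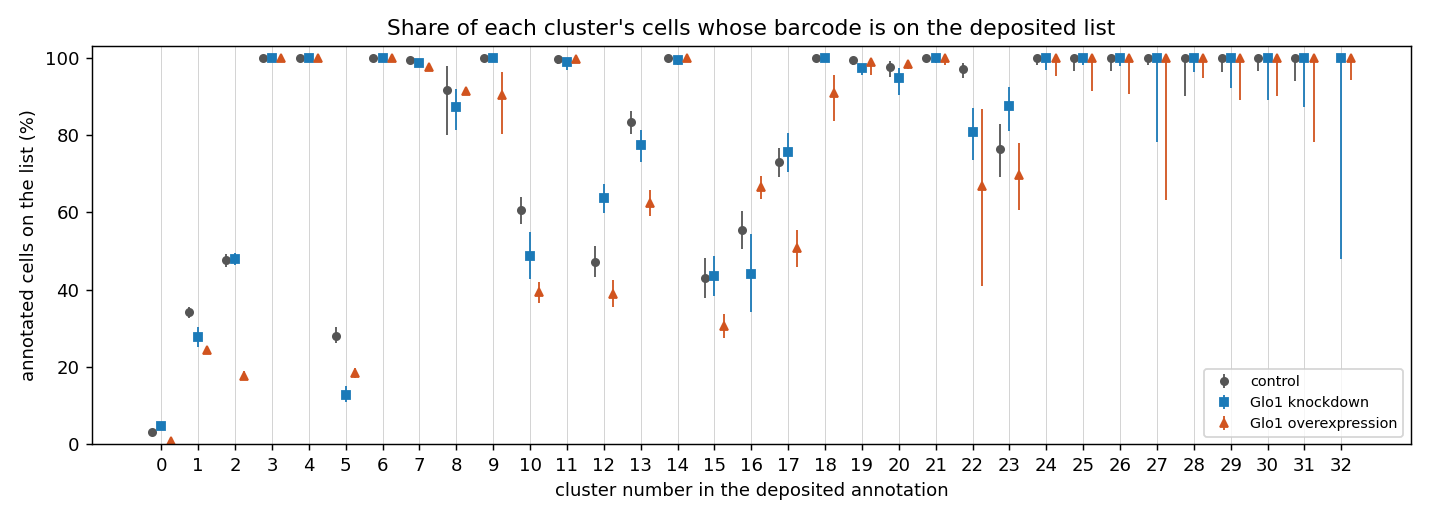
Percent of the annotated cells of each cluster (x axis) whose barcode was on the deposited list (y axis), for control (circles), knockdown (squares) and overexpression (triangles), with exact 95% intervals. Clusters 0, 1, 2, 5 and 15 lie below 50% in all 3 libraries, and cluster 32 has no control cells.

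Clusters 5, 15 and 20 passed no call among all annotated cells. Cluster 5 held 5.68%, 4.30% and 5.72% of the control, knockdown and overexpression cells. Cluster 15 held 1.09%, 1.44% and 1.40%, and cluster 20 held 0.877%, 0.745% and 1.06%.

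The feature list was identical in the 3 libraries, with 33696 genes, each with a mouse Ensembl identifier. Glo1 (ENSMUSG00000024026) and Sox2 (ENSMUSG00000074637) were both on it. In GENCODE M21 on GRCm38, Glo1 is a protein-coding gene on the minus strand of chromosome 17 from 30584936 to 30626871. It overlaps 1700097N02Rik, a long noncoding RNA gene on the same strand, and Dnah8, a protein-coding gene on the plus strand, and both were on the feature list. Sox2 is a protein-coding gene on the plus strand of chromosome 3 from 34650405 to 34652461. It lies within Sox2ot, a noncoding transcript on the same strand from 34104270 to 34682619 that was also on the list. No GFP or vector feature was on the list, so reporter reads were not assigned to a feature. All genes of the lists fixed in advance were present, among them 8 of methylglyoxal detoxification, 14 of glycolysis, 14 of stemness and 10 of the cell cycle. Expression per cell was not analysed here, so the level of Glo1 in the 3 libraries, which would check the labels, is not given, and no cluster could be named by its genes.

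Barcodes that recurred in different libraries were rare. Of the listed barcodes, 129 were shared by control and knockdown (Poisson interval 108 to 153), 201 by control and overexpression (174 to 231) and 153 by knockdown and overexpression (130 to 179). If barcodes were drawn at random, these overlaps correspond to pools of 3971812, 3315101 and 3433776 barcodes. Their intervals were 3342696 to 4757287, 2887180 to 3825740 and 2930834 to 4050102 barcodes. Annotated cells that shared a barcode across 2 of the libraries were in the same cluster in 8.33% (5.01 to 12.9%), 7.87% (5.88 to 10.3%) and 7.76% (5.44 to 10.7%) of cases. The compositions of the libraries predict 7.83%, 7.77% and 8.02%.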

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

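The tests on listed cells, on an effect of Glo1 overexpression, and on a shift of another cluster were chosen only after the result was seen, as were the denominator of all listed barcodes and the use of the planned removal of cluster 0 as a test of dilution. Barcodes that were on a library's list but absent from the annotation have no cluster number, and their share was above that of the control library in both other libraries. It was 33.0% in overexpression (8638 barcodes, interval 32.5 to 33.6%) and 11.1% in knockdown (2238 barcodes, 10.7 to 11.6%), against 9.60% in control (2447 barcodes, 9.24 to 9.97%).

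The high share of cluster 0 in overexpression was nearly confined to barcodes beyond the deposited list. Its gap to control among listed cells was 0.0302 times the gap among all annotated cells. With cluster 0 cells listed as often as in control, that ratio would already have been as low as 0.122. The ratio therefore does not decide why barcodes beyond the list were annotated or what these cells are, which stays open. An arithmetic split of the gap of 38.5 percentage points gave 18.9 to the larger unlisted share of the overexpression library. It gave 19.6 to the higher share of cluster 0 within the listed and unlisted parts. Cluster 0 held 65.0% of the unlisted overexpression cells and 27.8% of the unlisted control cells. The split does not separate sources of the gap, since cluster 0 cells were themselves mostly unlisted. Reads crossing from the other libraries are argued against, as cluster 0 barcodes recurred elsewhere 0.927 times as often as those of other overexpression cells. For barcode sequence errors of listed cells, 0 of the 29486 cluster 0 barcodes lay 1 base from their own list, so none differed by a single base from a listed barcode. As 0 lay 1 base from either of the other lists, the ratio set in advance could not be formed, and errors at more bases stay open, as untested. An effect of Glo1 overexpression cannot be told apart from the library, with a 3.98-fold excess left among listed cells.

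The gain of cluster 8 in overexpression did not come from unlisted barcodes, since it was 90.6-fold among listed cells. It did not come from fewer cells of other clusters in the denominator either, since with all listed barcodes as the denominator it was 67.1-fold. No single other cluster lost as much, since the largest loss, 10.3 percentage points in cluster 3, was 0.600 times the gain of 17.1 points. All losses together were 2.28 times the gain. Losses and gains of shares balance, so this sum could not lie below the gain and decides nothing. A shift of 1 cluster or of several stays open, as untested. An effect of Glo1 overexpression also stays open, with at least a 36.4-fold gain in every setting that kept the cluster. The setting without clusters mostly from 1 library left it out, as 93.8% of its cells were from overexpression. The design of 1 library per condition cannot separate such an effect from the library.

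Clusters 19, 21, 25 and 26 moved in opposite directions from control. A simulation of counting error around the shared control library gave as many in 0 of 200 sets, but it decides nothing, since the rule for a call already removes counting error, and variation between libraries of 1 condition stays open. Dilution by cluster 0 in the overexpression library is argued against as the whole of these moves, since 4 of the 4 kept both moves without it. Their losses in overexpression were smaller without it. The log2 ratio to control went from -2.20 to -1.41 in cluster 19 and from -1.56 to -0.77 in cluster 21. By centred log ratio cluster 21 lost its call in overexpression. For barcodes beyond the deposited list the result is mixed, since 3 of the 4 kept both moves among listed cells and cluster 21 did not. All 304 control and 194 overexpression cells of cluster 21 were listed. Its loss therefore went from 2.96-fold to 1.19-fold through the denominators alone. The losses of clusters 25 and 26, also fully listed, went from 4.79-fold to 1.93-fold and from 5.15-fold to 2.07-fold. No biological explanation was tested.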

How the results depend on the processing

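Only the removal of the largest cluster and the overlap of annotated barcodes were chosen before the data were examined, and all other settings in this part were chosen after. Of the 14 calls between knockdown and control, 13 were made in every setting that kept the cluster, as were 17 of the 25 between overexpression and control and 16 of the 25 between knockdown and overexpression. The setting without barcodes seen in another library ended 1 call, that of cluster 29 in knockdown, and reversed none. The number of clusters higher in overexpression than in control was 4 as reported, 10 without the largest cluster, 10 among listed cells, 8 with all listed barcodes as the denominator, 12 by centred log ratio, 8 without clusters mostly from 1 library and 7 without clusters mostly off the list. The number lower, 21 as reported, was 13 among listed cells and 13 without clusters mostly off the list. The number higher in knockdown than in overexpression, 18 as reported, was 10, 11 and 9 among listed cells, by centred log ratio and without clusters mostly off the list. The number lower, 7 as reported, was 11 among listed cells and 11 by centred log ratio. The number lower in knockdown and higher in overexpression than in control, 0 as reported, was 3 without the largest cluster and 3 among listed cells. The percent of cells that would have to change cluster, 17.0, 45.5 and 54.4 for knockdown with control, overexpression with control and knockdown with overexpression, was 18.0, 36.5 and 45.8 without the largest cluster, 15.8, 39.0 and 47.9 among listed cells, and 11.3, 42.7 and 47.3 without clusters mostly off the list. Without clusters mostly from 1 library it was 34.0 for overexpression with control and 42.5 for knockdown with overexpression. Directions reversed in these cases, given as log2 ratios of shares. For overexpression over control, cluster 12 was at 0.16 without the largest cluster, 0.41 among listed cells, 0.48 by centred log ratio and 0.31 without clusters mostly from 1 library. Cluster 13 was at 0.19, 0.29, 0.50 and 0.33 in the same order and at 0.75 without clusters mostly off the list. Cluster 14 was at 0.0025 among listed cells and 0.050 without clusters mostly off the list, where clusters 17 and 23 were at 0.11 and 0.0058. For knockdown over overexpression, cluster 17 was at -0.069 without the largest cluster, -0.069 among listed cells, -0.45 by centred log ratio, -0.21 without clusters mostly from 1 library and -0.72 without clusters mostly off the list. Cluster 14 was at -0.50 among listed cells, -0.096 with all listed barcodes as the denominator, -0.30 by centred log ratio, -0.066 without clusters mostly from 1 library and -0.57 without clusters mostly off the list. Cluster 6 was at -0.079 among listed cells and -0.15 without clusters mostly off the list. Without clusters mostly off the list, 2 of these turned into the opposite call: cluster 13 from lower to higher in overexpression than in control, and cluster 17 from higher to lower in knockdown than in overexpression. Beyond the changed denominators the cause was not tested. The barcode pools from annotated cells, 3865612, 3315858 and 3598744 barcodes, lay within the intervals from listed barcodes. The alternatives planned for cell types, cell-cycle phases, depth per cell and the embedding were not run, since the annotation used here gives cluster numbers only. The number of cells limits cluster 27, with 8 overexpression cells, and cluster 32, with 0 control and 5 knockdown cells. It also limits cluster 22, with 18 overexpression cells (0.0288%, 0.0171 to 0.0456%), of which 12 were listed. No paired analysis was possible because each condition has 1 library.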

Other observations

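Cluster 9 differed little between control and knockdown, at 7.08% and 6.89% of listed cells, and held 0.320% of listed overexpression cells, where 56 of its 62 annotated cells were listed. Cluster 18 followed the same pattern, at 2.76%, 2.60% and 0.560%. Cluster 20 was close in control and knockdown, at 1.23% and 0.997% of listed cells, and held 3.73% in overexpression. Among listed cells, the 5 largest clusters of each library held 57.5% of the control, 64.1% of the knockdown and 52.6% of the overexpression cells.

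Annotated cells that were not listed overlapped between libraries as a random draw from one barcode pool would. They shared 22 barcodes between control and knockdown, 146 between control and overexpression and 95 between knockdown and overexpression. The pools these imply are 3366286 barcodes (interval 2223421 to 5371493), 3089337 (2626990 to 3658731) and 3491672 (2856295 to 4315716), and each interval overlaps that of the listed barcodes. The 1684 gene identifiers absent from GENCODE M21 all carried numbers above the highest one in that release.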
